A study of Mus musculus with 12 samples.

How the data were processed

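ATAC-seq libraries had been made from nuclei of cells sorted by flow cytometry from mouse brain tumours (genotype Ink4a/Arf knockout with PDGFB). Per the labels' protocols, nuclei were permeabilised and tagmented with Tn5 made in the laboratory, and the DNA went through 2 rounds of PCR of 9 cycles each with selection of fragments between 150 and 700 bp. Per the submitters' processing notes, BWA 0.7.17-r1188, SAMtools 1.10, Picard 2.12.0, deepTools 3.5.1 and the mm10 build were used, without a stated role or order. The peak caller, the treatment of duplicates and any shift of reads for the transposase's binding are not given in the sources used here. The count values were used as deposited by the authors, as whole-number counts of 12 libraries in 117835 regions. The region identifiers name peaks and consensus peaks of the 4 groups that were merged into 1 set. MDM alone, the group with the most counts, is named for 44574 regions, against 6556 for MG, 1081 for LL-MDM and 1682 for LL-MG. No column was left without a sample (0 unmapped).

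Samples were grouped by their descriptions, which are the column names of the count table and give the lineage and lipid state. For 4 samples the titles and cell type labels name the same group as the description, and for 8 they differ. The groups by title were run as an alternative. Replicate numbers here follow the order of the samples within a group and pair nothing. The titles number 3 mice, and because titles and descriptions conflict, no library was tied to a mouse.

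Region counts were tested with edgeR 4.0.16 in R 4.3.3. Regions with low counts were removed with filterByExpr on the group, which left 77737, libraries were scaled with TMM, and 1 model over the 4 groups was fitted with glmQLFit (robust) and tested with glmQLFTest. The Benjamini-Hochberg adjusted p had to be under 0.05, with no minimum fold. The tests were MG against MDM, LL-MG against LL-MDM, LL-MDM against MDM, LL-MG against MG, the average of both lipid-load differences, and their interaction, which is the lipid-load difference in microglia minus that in MDM. Standard errors of log2 fold changes came from the fold change and its quasi-likelihood F value. CPM values used TMM-scaled totals, and principal components and correlations used log2 CPM with a prior count of 2. Region totals ranged from 1162969 to 18938222 counts, so that the smallest LL-MDM library holds about 1 count at a level of 1 CPM. PCR copies cannot be told from separate fragments in counts, so the spread between libraries, not the counting error, was used throughout.

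For gene loci, counts were summed over the regions that overlap the span of a protein-coding gene or the 5 kb on either side of it. The gene table (GRCm38.p6, the assembly of mm10) gives spans without strand, exons or transcription starts, so the 5 kb flank was taken on both sides in place of upstream alone, and whether a region is exonic, intronic or in a UTR is not known here. Of 21631 genes 16304 had a region and 15552 passed the filter. Of the 81229 regions assigned to a gene, 11098 were assigned to more than 1, so neighbouring genes share counts. Shared counts made up 100% for Apoe, Apoc1, P2ry12, Ccl3 and Tnf, 90.7% for S100a6, 86.7% for Cd63, 70.5% for Nr1h3, 52.9% for Zbtb46 and 50.8% for Mmp14. Single regions were named by the nearest gene span within 50 kb, in place of the nearest start, and 10.7% of regions lay farther from any gene.

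The 25 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover microglia identity, monocyte-derived macrophage identity, lipid uptake and storage, cholesterol efflux and LXR targets, PPAR and fatty acid oxidation, sterol biosynthesis, lipid-associated macrophages and disease-associated microglia, lysosome and autophagy, hypoxia and glycolysis, NF-kB targets, the interferon response, antigen presentation, immunosuppression and repair, matrix remodelling and angiogenesis, oxidative stress and proliferation. Lists of other cell types cover oligodendrocytes, astrocytes, neurons, endothelium, T and NK cells, B cells, neutrophils, dendritic cells and border-associated macrophages. Some genes are on more than 1 list (Apoe, Trem2, Lpl, Fn1 and Mrc1 among those named). Each list was tested with camera of limma 3.58.1 on voom values, with the preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists within a comparison. The members past the edgeR test were also counted after adjustment over the list alone.

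Named regions were those with the smallest p among the called ones with an absolute log2 fold change of at least 1 and no overlap between the libraries of the groups, up to 8 in each direction and 1 per gene. For the average the absence of overlap was asked in both lineages, and for the interaction it was not asked. Named genes were up to 4 members of each list past the test, by p, and a fixed set of lineage genes (Tmem119, P2ry12, Sall1, Ccr2, Itga4) and lipid genes (Gpnmb, Abca1, Abcg1, Apoe, Trem2, Lpl, Cd36, Fabp5, Plin2, Spp1, Pparg, Nr1h3). A part of these is given in the text, and some are not reported here.

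Alternatives were other scalings (RLE, total counts, loess offsets), other filters, DESeq2 1.42.0, limma-voom, a minimum fold, fits with only the groups compared, a replicate block, the titles' groups, and leaving out each library in turn. Added after the data were seen were fits with every library thinned to the smallest total, without MG 2 and MG 3 (and, for LL-MG against MG, with MG 2 or MG 3 as the only MG library), with regions named in all 4 groups, and with MDM libraries mixed with LL-MG reads as the reference for LL-MDM. For the last, regions specific to a lineage were those with an absolute log2 fold change over 4 and an adjusted p under 1e-04 between MG and MDM, 796 for microglia and 339 for MDM. Planned results on promoter shares and on motifs were not run, because the gene table has no transcription starts and no genome sequence was used here.

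The steps were tested on simulated counts drawn from the real means, spreads and library sizes, with 200 changed features. Of genes changed by a factor of 2, between 76.8% (interaction) and 94.9% (average) were recovered, and for a factor of 4 between 89.0% and 99.0%. Of regions changed by a factor of 2, 43.2% were recovered for LL-MDM against MDM and 35.9% for LL-MG against MG. The share was 44.1% for MG against MDM, 27.2% for LL-MG against LL-MDM, 78.3% for the average and 11.4% for the interaction. With only 200 changed features the adjusted threshold is stricter than in the data, where 8467 to 40163 regions were called. These shares therefore do not give the recovery in the data. False calls in this setting were 10.2% to 20.5% of region calls and 5.76% to 7.96% of gene calls, above the nominal level. In the simulation camera called the changed list, and 0 of 50 unchanged lists at an unadjusted p under 0.05. Tables were handled with the R package data.table (1.17.8) and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.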

Results

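Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase places sequencing adapters into open DNA, in macrophages sorted from mouse brain tumours driven by PDGFB in animals without Ink4a/Arf. Monocyte-derived macrophages (MDM), which enter the tumour from the blood, and microglia (MG), the resident macrophages of the brain, were each collected as lipid-laden cells (LL-MDM and LL-MG) and as cells without lipid load (MDM and MG). Each of the 4 groups had 3 libraries. The values were counts in 117835 consensus regions of the mm10 genome, with a median width of 179 bp, and 58.7% of the regions lay inside the span of a protein-coding gene. Region totals were 14216447, 18938222 and 6341183 counts for MDM libraries 1, 2 and 3, and 2753453, 6872724 and 4399328 for MG. They were 1162969, 7390521 and 3050059 for LL-MDM, and 2268884, 2150072 and 2764146 for LL-MG. Region identifiers named an MDM call for 105173 regions, an LL-MDM call for 50422, an MG call for 61019 and an LL-MG call for 42698. Below, a gene's accessibility is the sum of the regions inside its span or within 5 kb of it. Levels are CPM, counts scaled to the library total (mean ± SD, n = 3), and differences are log2 fold changes ± standard error from edgeR.

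The microglia regulator Sall1 was nearly closed in the 3 MDM libraries (0.830, 1.02 and 0.471 CPM) and open in the 3 MG libraries (71.4, 37.7 and 50.2 CPM) and in the 3 LL-MG libraries (63.4, 85.0 and 64.6 CPM). In the LL-MDM libraries it stood at 11.5, 9.42 and 5.94 CPM. The integrin gene Itga4, a marker of monocyte-derived cells in glioma, ran the other way, at 107 to 132 CPM in MDM and 38.4 to 48.6 CPM in MG, with 77.3 to 82.0 CPM in LL-MDM and 40.4 to 54.9 CPM in LL-MG. The first principal component of all tested regions held 53.5% of the variance and ordered the groups as MDM (-212 to -196), LL-MDM (-83.5 to -47.1), MG (68.3 to 137) and LL-MG (148 to 173). The second component (13.1%) set MG 2 (-175) and MG 3 (-110) apart from MG 1 (-8.74). The third (11.1%) set LL-MDM 1 (-176), the library with the fewest counts, apart from LL-MDM 2 (-30.4) and LL-MDM 3 (-46.8). Within groups, the median correlation between libraries on the log2 scale was 0.976 for MDM, 0.904 for MG, 0.891 for LL-MDM and 0.922 for LL-MG. Between groups it was 0.847 for MDM and LL-MDM, 0.865 for MG and LL-MG, 0.699 for MDM and MG, and 0.782 for LL-MDM and LL-MG. No pair of libraries in a group differed by less than the sampling noise.

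**Figure D1:**
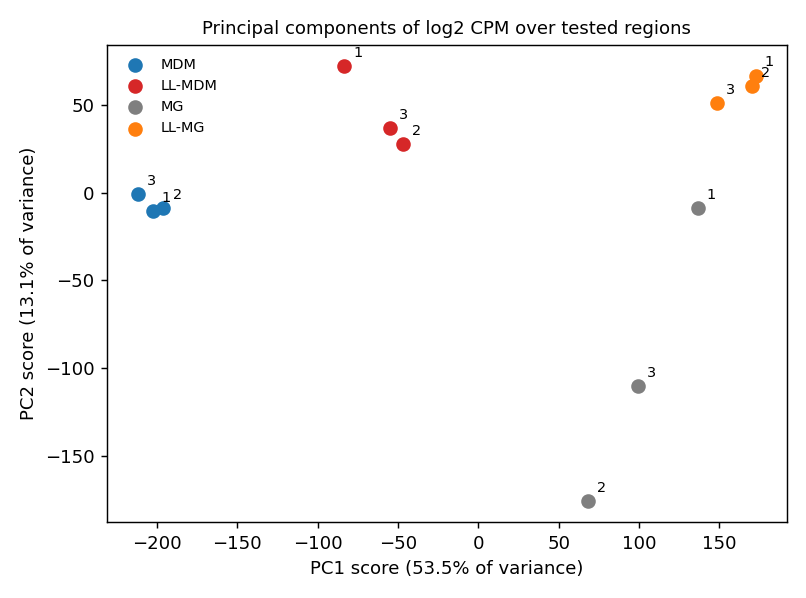
First against second principal component of log2 CPM over all tested regions, 1 point per library and 1 colour per group (3 libraries each). LL-MDM libraries sit between MDM and microglia on the first component, and MG 2 and MG 3 lie at -175 and -110 on the second.

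These groups come from the library names that head the count columns. For 8 of the 12 samples the sample titles give another group than the library name, and the titles and the names cannot both be right. With the titles' groups, edgeR called 0 of 77737 regions between MG and MDM (183 at an unadjusted p under 0.05). Between LL-MG and LL-MDM it called 0 (857 at an unadjusted p under 0.05). LL-MDM against MDM gave 13770 and LL-MG against MG 8252, but not the lipid-load differences found by the library names. In both the monocyte-derived identity list was lower (limma's camera, adjusted p = 4.32e-06 and 3.07e-05), as in MG against MDM by the library names. Across regions these lipid-load differences correlated with r = 0.905. Each difference between lineages and between lipid loads reported here therefore rests on the library names. The titles number 3 mice, but no label ties a library to a mouse beyond doubt, so the p-values measure the spread between these libraries, part of which may be technical.

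Microglia and MDM without lipid load were compared first, since the lineage difference is the background to the effect of lipid. In MG, Sall1 rose from 0.775 ± 0.280 to 53.1 ± 17.0 CPM (5.88 ± 0.29), the related zinc-finger gene Sall3 from 3.28 ± 0.528 to 26.8 ± 9.90 (2.92 ± 0.23), and the Fc receptor-like gene Fcrls from 5.71 ± 0.716 to 15.7 ± 4.64 (1.39 ± 0.22). The surface genes Tmem119 (0.51 ± 0.12) and P2ry12 (0.67 ± 0.20) rose less (edgeR, adjusted p = 0.00152 and 0.0185). The P2ry12 call was lost without MG 3 (adjusted p = 0.0645 in edgeR) and with every library thinned to the smallest total (adjusted p = 0.0605), and all of its counts are shared with neighbouring genes. In MDM the MHC class II gene H2-Aa (200.1 ± 5.12 against 24.9 ± 4.83 CPM; -3.06 ± 0.11), Itga4 (-1.46 ± 0.11), the calcium-binding protein gene S100a6 (-1.08 ± 0.11) and Ms4a7 (-1.36 ± 0.14) were higher. Ccr2, the chemokine receptor of monocytes, did not differ by the test (0.20 ± 0.31, adjusted p = 0.639 in edgeR), with 9.86, 40.6 and 27.1 CPM in the 3 MG libraries and 23.8 ± 2.31 in MDM. Without MG 1 it was higher in MG (0.54, adjusted p = 0.00295 in edgeR), without MG 2 the difference was -0.28, and without MG 2 and MG 3 it was lower in MG (-1.28, adjusted p = 0.000176). In that fit MG is 1 library, MG 1, which is assumed to vary like the other groups.

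Of the 18 measured members of the microglia identity list, 8 were higher in MG and 1 lower (8 and 1 adjusted over the list alone). Limma's camera called the list, with adjusted p = 0.0214 and adjusted p = 0.538 with an estimated correlation. The monocyte-derived identity list ran the other way, with 12 lower in MG and 2 higher of 17 (13 and 2 adjusted over the list alone). As a set it passed limma's camera at adjusted p = 0.000181, and had adjusted p = 0.282 with an estimated correlation. Antigen presentation had 11 of 15 members lower and 0 higher (11 and 0 adjusted over the list alone). In limma's camera the set had adjusted p = 2.78e-06, and adjusted p = 0.282 with an estimated correlation. Dendritic-cell markers were lower too, 4 of 8 (4 adjusted over the list alone), led by the chemokine receptor Ccr7 (-2.72 ± 0.15) and the growth-factor receptor Flt3 (-1.57 ± 0.10). Its camera call in limma had adjusted p = 0.0133, and adjusted p = 0.282 with an estimated correlation. The immunosuppression list had 9 of 14 members lower and 2 higher (9 and 2 adjusted over the list alone; limma's camera, adjusted p = 0.00465; adjusted p = 0.211 with an estimated correlation). Its lower members included Cd274, which encodes PD-L1 (-0.85 ± 0.08), the mannose receptor gene Mrc1 (-1.03 ± 0.11) and Il10 (-0.79 ± 0.09). Among matrix genes 9 of 15 were lower and 2 higher (9 and 2 adjusted over the list alone), at adjusted p = 0.0422 in limma's camera and adjusted p = 0.323 with an estimated correlation, with the basement-membrane collagen gene Col4a1 at -1.74 ± 0.11 and the metalloproteinase gene Mmp14 at -1.27 ± 0.11. Interferon-response genes had 8 of 15 lower and 1 higher (8 and 1 adjusted over the list alone). The camera test of limma gave adjusted p = 0.0428, and adjusted p = 0.375 with an estimated correlation.

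The oxidised-LDL receptor gene Olr1 (-1.21 ± 0.10) and the fatty-acid scavenger receptor gene Cd36 (-0.77 ± 0.11) were lower in MG, while the lysosomal protease gene Ctsd (1.48 ± 0.10) and the growth-factor gene Csf1 (0.93 ± 0.10) were higher and the beta-glucan receptor gene Clec7a lower (-1.83 ± 0.14). The lipid-associated list that holds Ctsd, Csf1 and Clec7a had 8 members higher and 5 lower of 20 (8 and 5 adjusted over the list alone) and no call in limma's camera (adjusted p = 0.114). The inflammatory genes Ccl4 (1.37 ± 0.12), Ccl3 (1.17 ± 0.12) and Tnf (0.57 ± 0.09) were higher in MG. Slc1a3, an astrocyte glutamate transporter gene, was also higher, at 8.29 ± 2.28 CPM in MDM and 38.7 ± 18.1 in MG (2.09 ± 0.30). The strongest single regions were inside Nova1 (chromosome 12, 46819330 to 46819744; 6.73 ± 0.28), Sall1 (chromosome 8, 89042724 to 89043350; 6.09 ± 0.28) and Kcnma1 (chromosome 14, 23839618 to 23840009; 6.17 ± 0.30), which were near closed in MDM (0.245 to 0.420 CPM). Regions inside Alpk2 (chromosome 18, 65304677 to 65305295; -3.89 ± 0.18) and 15456 bp from Lonrf2 (chromosome 1, 38777352 to 38778213; -3.10 ± 0.16) were lower in MG.

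In all, 40163 of 77737 tested regions differed, 20804 higher and 19359 lower in MG (9759 and 5378 among the regions named in all 4 groups, a choice made after the data were seen). At gene level 6375 of 15552 genes differed, 3074 higher and 3301 lower. Without MG 2 and MG 3 the counts were 29479 regions and 5052 genes. List calls lost in other fits were those of the interferon list (camera, adjusted p = 0.104 without MDM 1, 0.178 without MG 2, 0.496 without MG 2 and MG 3 and 0.210 with thinned libraries), the matrix list (0.0659 without MG 1, 0.104 without MG 2, 0.117 without MG 2 and MG 3 and 0.0503 with thinned libraries) and the microglia list (0.0858 without MG 1). The count of lower interferon genes fell from 8 to 4 without MDM 1, to 4 without MG 2 and to 3 without MG 3. The lipid-associated list gained a camera call without MG 2 (adjusted p = 0.0418) and without MG 2 and MG 3 (0.0143), and without MDM 3 the hypoxia list did (0.0484).

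The same lineages were then compared among lipid-laden cells. Sall1 was at 8.95 ± 2.80 CPM in LL-MDM and 71.0 ± 12.1 in LL-MG (3.03 ± 0.26), the fractalkine receptor gene Cx3cr1 at 135 ± 9.77 and 195 ± 5.97 (0.53 ± 0.09), and P2ry12 was higher in LL-MG by 0.95 ± 0.23. Tmem119 did not differ by the test (-0.34 ± 0.13, adjusted p = 0.0634 in edgeR), though it was lower in LL-MG with thinned libraries (-0.47, adjusted p = 0.0364), and Ccr2 did not differ either (-0.97 ± 0.58, adjusted p = 0.278). Col4a1 (-1.54 ± 0.13), Ms4a7 (-1.11 ± 0.16), the fibronectin gene Fn1 (-1.05 ± 0.14), Mmp14 (-0.90 ± 0.12), Itga4 (-0.73 ± 0.13) and the hyaluronan receptor gene Cd44 (-0.72 ± 0.09) were higher in LL-MDM. So were Gpnmb (58.0 ± 7.49 against 25.5 ± 2.65 CPM; -1.15 ± 0.15) and Olr1 (-0.75 ± 0.13). In LL-MG the cholesterol exporter gene Abcg1 (0.67 ± 0.13), Ctsd (0.88 ± 0.11) and Tnf (0.55 ± 0.09) were higher, as were the glial genes Slc1a3 (2.15 ± 0.35) and Cspg4, which encodes the progenitor proteoglycan NG2 (1.58 ± 0.18). Each of these calls had an adjusted p of at most 0.0138 in edgeR, and that of P2ry12 was lost without LL-MDM 2 (adjusted p = 0.0552).

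The monocyte-derived identity list had 9 of 17 members lower and 0 higher in LL-MG (11 and 1 adjusted over the list alone). With limma's camera adjusted p = 7.23e-07 was found, and adjusted p = 0.206 with an estimated correlation. The microglia list had 8 of 18 higher and 0 lower (12 and 1 adjusted over the list alone), at adjusted p = 0.00101 in limma's camera and adjusted p = 0.504 with an estimated correlation, and its count fell from 8 to 5 without LL-MDM 3 and without LL-MG 2. The immunosuppression list had 6 of 14 lower and 1 higher (8 and 2 adjusted over the list alone). Limma's camera called the list, with adjusted p = 0.00482 and adjusted p = 0.206 with an estimated correlation. Matrix genes had 6 of 15 lower and 2 higher (6 and 3 adjusted over the list alone). As a set it passed limma's camera at adjusted p = 0.0156, and had adjusted p = 0.262 with an estimated correlation. Of the astrocyte markers 3 of 8 were higher (4 adjusted over the list alone), at adjusted p = 0.0288 in limma's camera and adjusted p = 0.262 with an estimated correlation, and of the neutrophil markers 3 of 7 were lower (3 adjusted over the list alone). In limma's camera the set had adjusted p = 0.0307, and adjusted p = 0.206 with an estimated correlation. The astrocyte call was lost without LL-MDM 2 (camera, adjusted p = 0.143), and the neutrophil call without LL-MG 2 (0.0582) and with thinned libraries (0.206). Antigen presentation, which split the lineages without lipid load, had 1 of 15 members lower here and 0 higher (1 and 0 adjusted over the list alone; median 0.02, mean -0.10; camera, adjusted p = 0.419, direction down).

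Regions inside Rbfox1 (chromosome 16, 6842122 to 6842661; 3.55 ± 0.28) and Pxk (chromosome 14, 8111585 to 8112287; 2.28 ± 0.19) were higher in LL-MG. Regions inside the ubiquitin ligase gene Nedd4l (chromosome 18, 64971850 to 64972516; -4.82 ± 0.28) and 10528 bp from Cd83 (chromosome 13, 43774138 to 43774584; -2.78 ± 0.23), an activation marker of dendritic cells, were lower. The Nedd4l region was as open in MDM (40.6 ± 2.91 CPM) as in LL-MDM (40.2 ± 2.60 CPM). Of 77737 regions 16704 differed, 8017 higher and 8687 lower in LL-MG. The larger part turned with the scaling and the tool, to 8562 higher and 8169 lower with RLE, 8928 and 7910 with loess offsets, 6480 and 6317 in DESeq2 and 7392 and 6511 in limma-voom, but not with total counts (8064 and 8421). The count was 10384 without LL-MDM 2. At gene level 3158 genes differed, 1865 higher and 1293 lower. Regions higher in microglia with and without lipid load numbered 6585, and regions lower in both 6455, where independent lists would share 2146 and 2163.

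Lipid-laden MDM were compared with MDM to ask which loci differ with lipid load. Gpnmb, a gene of lipid-associated macrophages, rose from 28.5 ± 3.43 to 58.0 ± 7.49 CPM (0.97 ± 0.12), the cholesterol exporter gene Abca1 from 230.5 ± 16.1 to 382 ± 20.8 (0.74 ± 0.11), and Plin2, which encodes the coat protein of lipid droplets, from 43.1 ± 0.515 to 64.8 ± 3.04 (0.59 ± 0.12). The lipoprotein genes Apoe (0.66 ± 0.11) and Apoc1 (1.85 ± 0.31), which are neighbours and share all of their counts with other genes, also rose. MHC class II loci fell, H2-Aa from 200.1 ± 5.12 to 50.5 ± 6.28 CPM (-2.01 ± 0.10) and H2-Eb1 from 237 ± 9.48 to 66.1 ± 8.84 (-1.83 ± 0.11). Each of these 7 calls had an adjusted p of at most 0.00103 in edgeR.

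The lipid-associated list, which combines genes of lipid-associated macrophages and disease-associated microglia, had 10 of 20 members higher and 2 lower (11 and 2 adjusted over the list alone). Its camera call in limma had adjusted p = 0.000497, and adjusted p = 0.0512 with an estimated correlation. Beside Gpnmb and Apoe it held the lysosomal membrane gene Cd63 (0.82 ± 0.08, 86.7% of its counts shared with neighbours), Ctsd (0.90 ± 0.11) and Trem2, a lipid-sensing receptor gene (0.71 ± 0.19). Its count of higher members fell to 6 without LL-MDM 2 and without MDM 2. Of the 15 PPAR and fatty acid oxidation genes 4 were higher and 0 lower (5 and 0 adjusted over the list alone), among them Angptl4 (0.68 ± 0.10), a lipase inhibitor gene and PPAR target, the oxidation enzyme gene Acadl (0.59 ± 0.10) and the receptor gene Ppard (0.36 ± 0.09). The camera test of limma gave adjusted p = 0.0337, and adjusted p = 0.285 with an estimated correlation. Cholesterol efflux genes had 5 of 14 higher and 0 lower (5 and 0 adjusted over the list alone), including the phospholipid enzyme gene Lpcat3 (0.44 ± 0.08), but no camera call (adjusted p = 0.0562). Leaving out LL-MDM 1 (0.0378), LL-MDM 3 (0.0256), MDM 1 (0.0455) or MDM 3 (0.0488) gave that list a call in limma's camera. Of the lipid uptake genes 5 of 17 were higher and 1 lower (6 and 1 adjusted over the list alone; camera, adjusted p = 0.158), with the endocytic receptor gene Lrp1 at 0.47 ± 0.10 and the lipase gene Lpl rising from 2.21 ± 0.603 to 4.50 ± 1.07 CPM (1.07 ± 0.33). Sterol biosynthesis had 2 of 14 higher and 1 lower (2 and 1 adjusted over the list alone; camera, adjusted p = 0.930), and the lower member was Srebf2, the regulator of sterol synthesis (-0.49 ± 0.08). Abcg1 (0.15 ± 0.12), Cd36 (0.13 ± 0.11), Fabp5 (0.32 ± 0.13), Spp1 (0.14 ± 0.15), Pparg (-0.10 ± 0.09) and the LXR gene Nr1h3 (-0.08 ± 0.08) did not pass the test.

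Antigen presentation fell, with 9 of 15 members lower and 0 higher (9 and 0 adjusted over the list alone), at adjusted p = 9.19e-09 in limma's camera and adjusted p = 0.251 with an estimated correlation; besides H2-Aa and H2-Eb1 these included H2-Ab1 (-1.31 ± 0.09) and the invariant chain gene Cd74 (-1.23 ± 0.09). Markers of dendritic cells fell with them, 6 of 8 lower and 0 higher (6 and 0 adjusted over the list alone). With limma's camera adjusted p = 0.000947 was found, and adjusted p = 0.123 with an estimated correlation. Ccr7 went from 78.8 ± 8.22 to 25.5 ± 7.42 CPM (-1.72 ± 0.14), Flt3 changed by -0.87 ± 0.10 and the transcription factor gene Zbtb46 by -0.34 ± 0.08. Of the same dendritic-cell markers, 6 of 8 also stood above 20 CPM in MG. The monocyte-derived identity list had 5 of 17 members lower and 1 higher (5 and 2 adjusted over the list alone; camera, adjusted p = 0.107), with Plac8 at -0.98 ± 0.13 and Itga4 at -0.56 ± 0.11. In the immunosuppression list 4 of 14 were higher and 3 lower (6 and 3 adjusted over the list alone; camera, adjusted p = 0.559), with Arg1, the arginase gene, at 0.64 ± 0.15 and Havcr2, which encodes TIM-3, at -0.76 ± 0.12.

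Among microglia genes, Sall1 rose in LL-MDM by 3.30 ± 0.39, though its level in LL-MDM (8.95 ± 2.80 CPM) stayed below that in MG (53.1 ± 17.0 CPM), and Tmem119 rose from 30.5 ± 3.37 to 70.7 ± 6.27 CPM (1.20 ± 0.12). The microglia list had 7 of 18 members higher and 0 lower (7 and 0 adjusted over the list alone). Limma's camera called the list, with adjusted p = 0.0422 and adjusted p = 0.601 with an estimated correlation. At 796 regions specific to microglia, LL-MDM libraries 1, 2 and 3 reached 11.2%, 18.1% and 15.6% of the LL-MG level above that of MDM (14.9 ± 3.49% SD, n = 3). Against MDM libraries mixed in silico with LL-MG reads at that share, a comparison added after the data were seen, the Sall1 difference was -0.38 (adjusted p = 0.161 in edgeR) and the microglia list lost its call (camera, adjusted p = 0.348). Tmem119 (1.04, adjusted p = 1.17e-17 in edgeR) and 4 others of the 7 higher members were still higher than in that reference, and Sall1 and Sall3 were not. The microglia list also lost its call without LL-MDM 2 (0.0724), MDM 2 (0.0906) or MDM 3 (0.0737), and its count of higher members was 4 without LL-MDM 2.

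Matrix genes had 4 of 15 members higher and 1 lower (6 and 1 adjusted over the list alone). As a set it passed limma's camera at adjusted p = 0.0337, and had adjusted p = 0.353 with an estimated correlation. The protease inhibitor gene Timp2 (1.08 ± 0.10), the urokinase gene Plau (0.76 ± 0.12) and the thrombospondin gene Thbs1 (0.67 ± 0.11) were among those higher. Lysosome and autophagy genes had 5 of 20 higher and 1 lower (5 and 1 adjusted over the list alone). In limma's camera the set had adjusted p = 0.0422, and adjusted p = 0.420 with an estimated correlation. Without LL-MDM 2 the matrix call (camera, adjusted p = 0.0724) and the lysosome call (0.0851) were lost, and without MDM 2 likewise (0.0888 and 0.117). With thinned libraries the matrix list (0.118) and the microglia list (0.0652) lost their camera calls in limma, and the cholesterol efflux list gained one (0.0436). The count of higher lysosome genes was 1 without LL-MDM 2, 2 without LL-MDM 3, 3 without MDM 1 and 2 without MDM 2. Other lists had no camera call. Hypoxia genes had 2 higher and 0 lower of 18, 0 and 0 adjusted over the list alone, NF-kB targets 0 higher and 2 lower of 17 (median 0.02, mean -0.03, camera direction down), interferon genes 2 higher and 3 lower of 15, oxidative stress genes 1 higher and 1 lower of 15 and proliferation genes 0 higher and 4 lower of 12, 0 and 5 adjusted over the list alone. Among markers of other cell types, oligodendrocyte genes had 1 higher and 3 lower of 11 (median -0.26, mean 0.02, camera direction down), astrocyte genes 0 higher and 0 lower of 8, neuronal genes 0 higher and 1 lower of 4 and endothelial genes 0 higher and 2 lower of 6. T and NK cell genes had 0 higher and 2 lower of 10, B cell genes 0 higher and 1 lower of 8, neutrophil genes 0 higher and 1 lower of 7 and border-associated macrophage genes 1 higher and 0 lower of 8. Where no second pair is given, the counts adjusted over the list alone were identical.

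**Figure D2:**
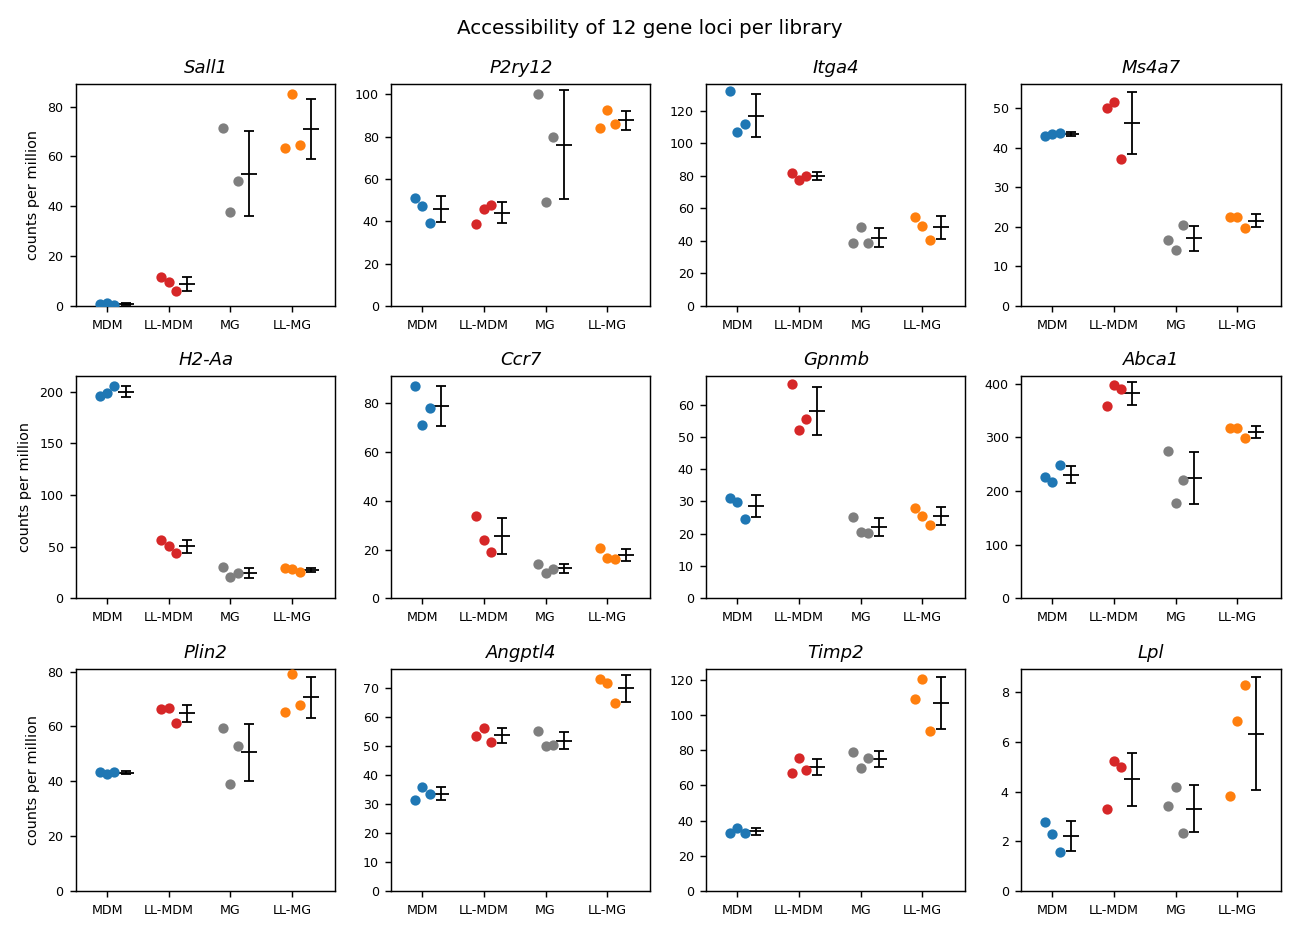
Accessibility in CPM at 12 gene loci in the 4 groups, with 1 point per library and a dash and bar for the mean ± SD (n = 3). H2-Aa and Ccr7 are lower and Gpnmb, Abca1, Plin2 and Timp2 higher in LL-MDM than in MDM, and Sall1 is lowest in MDM.

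The strongest regions higher in LL-MDM lay inside Gramd1b, a sterol transfer protein gene (chromosome 9, 40321003 to 40321926; 25.8 ± 4.57 to 123 ± 7.67 CPM, 2.27 ± 0.14), inside Zdhhc14 (chromosome 17, 5569109 to 5569953; 2.32 ± 0.15), inside Lhfpl2 (chromosome 13, 94169369 to 94169705; 2.71 ± 0.18) and 9413 bp from Gas6, a ligand of phagocytic receptors (chromosome 8, 13503948 to 13504502; 2.57 ± 0.19). Regions inside H2-Eb1 (chromosome 17, 34305648 to 34306119; -2.05 ± 0.15) and Zbtb46 (chromosome 2, 181436193 to 181436598; 21.4 ± 2.03 to 1.54 ± 0.441 CPM, -3.74 ± 0.29) fell. In all, 22966 of 77737 regions differed, 11998 higher and 10968 lower in LL-MDM (6396 and 2767 among the regions named in all 4 groups). Of 15552 genes 3708 differed, 1817 higher and 1891 lower. The region count was 11846 without LL-MDM 2, and the gene count was 2146 without LL-MDM 2, 2262 without LL-MDM 3 and 2366 without MDM 1. Single calls were lost in edgeR for Lpl without LL-MDM 2 (adjusted p = 0.182), LL-MDM 3 (0.0770) or MDM 2 (0.0645), for Trem2 without LL-MDM 2 (0.0583), LL-MDM 3 (0.0704), MDM 1 (0.0533) or MDM 2 (0.0544), and for Arg1 without LL-MDM 2 (0.0580). With every library thinned to the smallest total, the calls of Trem2 (0.107), Zbtb46 (0.0955) and Thbs1 (0.0850) were lost, and the differences of Fabp5 (-0.06) and Pparg (0.00) changed sign without a call.

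In microglia fewer loci were called with lipid load than in MDM. Plin2 rose from 50.5 ± 10.5 to 70.6 ± 7.41 CPM (0.52 ± 0.13), Abca1 from 224 ± 48.3 to 311 ± 11.1 (0.48 ± 0.11) and Lrp1 from 334 ± 65.3 to 469 ± 27.9 (0.50 ± 0.11). The nucleic acid sensor gene Zbp1 (0.73 ± 0.14) and the antiviral membrane gene Bst2 (0.60 ± 0.13) also rose, as did Il1rn, the interleukin-1 receptor antagonist gene (0.82 ± 0.15). The chemokine gene Ccl4 fell from 330.4 ± 76.0 to 234 ± 18.8 CPM (-0.51 ± 0.13). Each of these 7 calls had an adjusted p of at most 0.0153 in edgeR. Without MG 2 and MG 3, the libraries set apart on the second principal component, edgeR called 42 regions and 16 genes. MG is then 1 library, assumed to vary like the other groups, and with MG 2 alone or MG 3 alone in its place the counts were 26909 and 9325 regions and 6400 and 2805 genes. The genes that the text gives by the naming rule as higher in LL-MG, also 16, were all still higher against MG 1 alone, but none passed the test, and their median difference went from 0.52 to 0.29 (0.09 to 0.62).

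Interferon-response genes had 6 of 15 members higher and 0 lower (6 and 0 adjusted over the list alone). Its camera call in limma had adjusted p = 0.00405, and adjusted p = 0.400 with an estimated correlation. Matrix genes had 5 of 15 higher and 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 0.0168 in limma's camera and adjusted p = 0.400 with an estimated correlation, with Timp2 at 0.52 ± 0.10, Plau at 0.53 ± 0.13 and Thbs1 at 0.53 ± 0.14. The lipid-associated list had 4 of 20 higher and 0 lower (9 and 0 adjusted over the list alone), Apoe among them (0.38 ± 0.12). The camera test of limma gave adjusted p = 0.0248, and adjusted p = 0.344 with an estimated correlation. The microglia list had 1 of 18 higher and 1 lower (8 and 1 adjusted over the list alone). With limma's camera adjusted p = 0.00595 was found, and adjusted p = 0.455 with an estimated correlation. Cholesterol efflux genes had 5 of 14 higher and 0 lower (5 and 1 adjusted over the list alone; camera, adjusted p = 0.179), including Nr1h3, the gene of LXR alpha (0.42 ± 0.09, 70.5% of its counts shared with neighbours), and Abcg1 (0.39 ± 0.12). PPAR genes had 4 of 15 higher and 0 lower (4 and 0 adjusted over the list alone; camera, adjusted p = 0.121), including Ppard (0.44 ± 0.09) and Angptl4 (0.44 ± 0.10). Antigen presentation, which fell in LL-MDM, had 4 of 15 higher and 0 lower (4 and 0 adjusted over the list alone; camera, adjusted p = 0.103), among them Ciita, the MHC class II transactivator gene (0.70 ± 0.14). Cspg4 rose by 0.80 ± 0.16, and the oligodendrocyte list that holds it had 2 of 11 higher and 0 lower (3 and 0 adjusted over the list alone; camera, adjusted p = 0.107). Gpnmb (0.23 ± 0.16), Trem2 (0.55 ± 0.20), Lpl (0.92 ± 0.36), Cd36 (0.34 ± 0.13), Fabp5 (0.32 ± 0.14), Spp1 (-0.11 ± 0.19) and Pparg (-0.06 ± 0.11) did not pass the test.

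**Figure D3:**
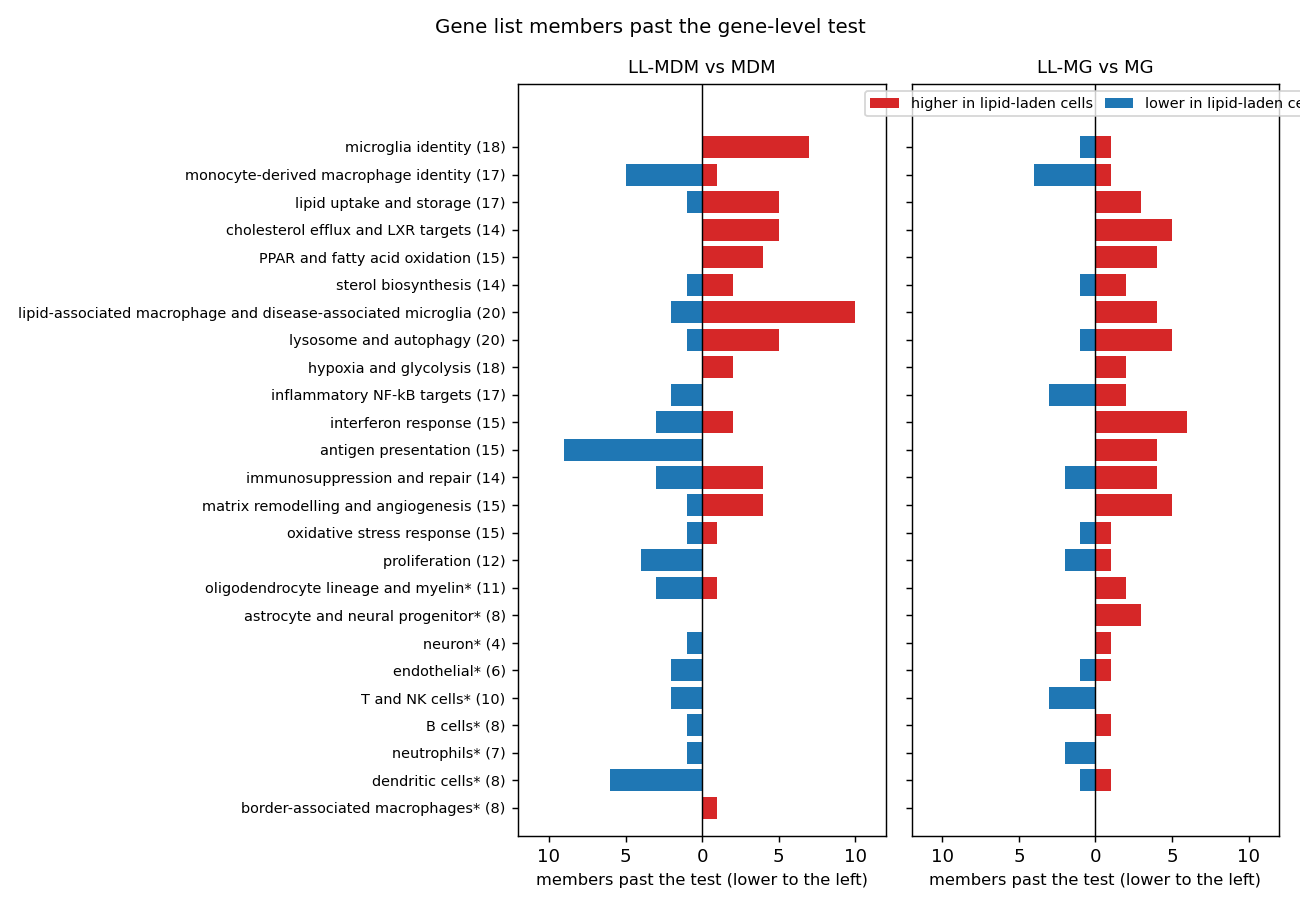
Number of measured members of each gene list past the edgeR test, drawn to the right where higher and to the left where lower in lipid-laden cells, for LL-MDM against MDM and LL-MG against MG. Brackets give the measured members and an asterisk marks a list of another cell type; antigen presentation has 9 lower members in LL-MDM and 4 higher in LL-MG.

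The libraries MG 2 and MG 3 also stood apart at loci of basophils and mast cells, from a list of 21 genes written after this was seen. Of these, 6 had been seen to stand apart before they were listed, and 5 were added once values of others on the list were known. At Il13 the 3 MG libraries had 14.6, 104 and 56.1 CPM, and the highest of the 9 libraries of the other groups and MG 1 had 14.6. At Hdc, the histidine decarboxylase gene, MG 1, 2 and 3 had 46.2, 197 and 115 CPM against at most 55.0 elsewhere, and at Gata2 47.6, 116 and 83.0 against 50.2. Of the 16 measured genes on the list 13 (81.2%) were higher in MG 2 and MG 3 than in each of the other 10 libraries, against 8.32% of all genes. Among the 7 measured genes listed earlier and without having been seen to stand apart in these libraries, 5 (71.4%) were higher, at Hgf by little (42.5 CPM in MG 3 against 41.6). Il1rl1 was not, nor was Kit, which had been seen before among the genes of the first principal component.

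**Figure D4:**
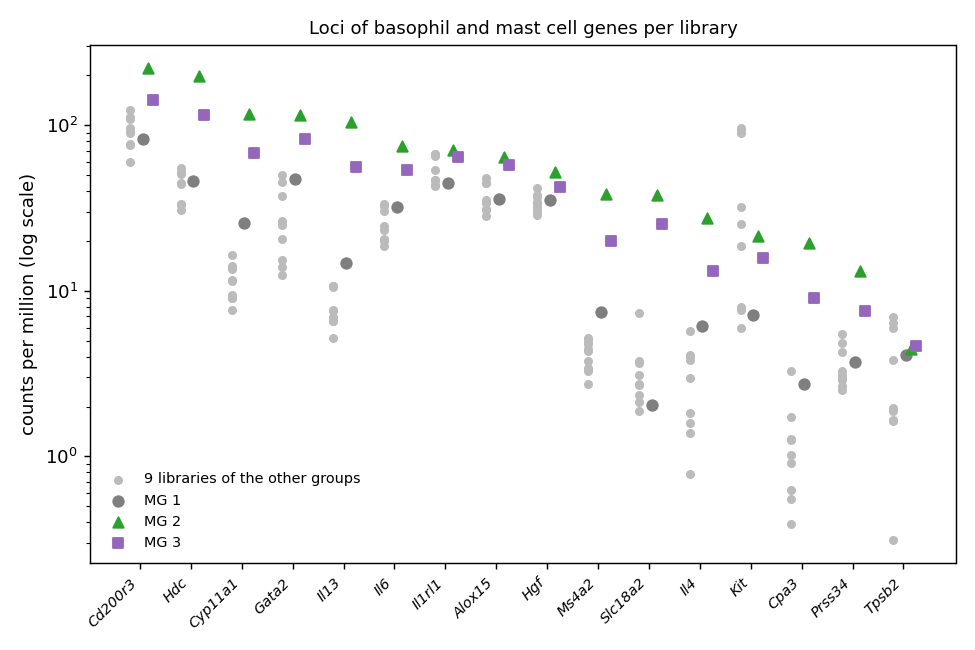
Accessibility in CPM, on a log axis, at 16 loci of basophils and mast cells in MG 1, MG 2 and MG 3 and in the 9 libraries of the other groups. MG 2 and MG 3 exceed the other 10 libraries at 13 of the 16 loci and not at Kit, Il1rl1 and Tpsb2.

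Single regions that rose in LL-MG lay inside Stk40 (chromosome 4, 126137763 to 126138141; 5.52 ± 1.14 to 20.4 ± 2.23 CPM, 1.91 ± 0.24), inside Nr1h3 (chromosome 2, 91196722 to 91197250; 1.21 ± 0.17) and 7536 bp from Efna1 (chromosome 3, 89288487 to 89288948; 1.39 ± 0.21). Regions 19 bp from Neurl3 (chromosome 1, 36264174 to 36264583; -1.41 ± 0.19) and inside Serinc3 (chromosome 2, 163642677 to 163643179; -1.16 ± 0.17) fell. Without MG 2 and MG 3 the Stk40 (1.61, adjusted p = 0.0136 in edgeR) and Nr1h3 (1.08, 0.0198) regions kept their calls, and those at Efna1 (0.110), Neurl3 (0.0673) and Serinc3 (0.109) lost them. Genes called against MG 1 alone, named here after their values were seen, included Col27a1 (0.99), Zdhhc18 (0.61), Aph1b (0.71), Slc31a2, Bmp8a, Rab12, Phldb1, Slc37a2, Sphk1, Nod1 and Cdk18, which were higher in LL-MG, and Olfr70 and Cytip, which were lower. With the 12 libraries, 9502 of 77737 regions differed, 3276 higher and 6226 lower in LL-MG. Of 15552 genes 2847 differed, 1606 higher and 1241 lower. The share of regions called higher depended on the scaling: it was 34.5% with TMM and 48.0% with total counts (4835 higher and 5243 lower), which move the median of all regions from 0.00 to 0.11, and 53.8% in limma-voom (3312 and 2846).

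The counts moved with single libraries. Regions numbered 3869, 4129 and 4263 without LL-MG 1, 2 or 3, 22310 without MG 1 and 3029 without MG 2. Genes numbered 999, 1114 and 1248 without LL-MG 1, 2 or 3, and 5915, 1044 and 1396 without MG 1, 2 or 3. In edgeR the call of Apoe was lost without LL-MG 1 (adjusted p = 0.0932), LL-MG 2 (0.162), LL-MG 3 (0.0683), MG 2 (0.115) or MG 3 (0.0927), and that of Abcg1 without LL-MG 1 (0.173), LL-MG 2 (0.114), MG 2 (0.107) or MG 3 (0.126). Plin2 was lost without LL-MG 2 (0.0739) or MG 2 (0.0620), Thbs1 without LL-MG 2 (0.0649) or LL-MG 3 (0.0781), Plau without LL-MG 1 (0.0554) and Ccl4 without LL-MG 3 (0.0668). Without MG 1, Cd36 (0.00318), Trem2 (0.0326) and Fabp5 (0.0429) gained calls. With every library thinned to the smallest total, Abcg1, Angptl4, Apoe, Bst2, Ciita, Nr1h3, Plin2, Thbs1 and Timp2 lost theirs (adjusted p = 0.0521 to 0.242 in edgeR). In limma's camera the lipid-associated list lost its call without MG 1 (adjusted p = 0.0676) or MG 3 (0.0580), the matrix list without MG 1 (0.0676) and the microglia list without MG 2 (0.0894) and, with its direction turned to down, without MG 2 and MG 3 (0.657), and the lysosome list gained one without LL-MG 3 (0.0479). With thinned libraries the lipid-associated list lost its call (0.0605), and the immunosuppression list gained one there (0.0473) and without MG 2 and MG 3 (0.0128). The higher interferon genes numbered 3 without LL-MG 1, LL-MG 2, MG 2 or MG 3, the higher matrix genes 2 without LL-MG 1 or LL-MG 2 and 3 without LL-MG 3, MG 2 or MG 3. The higher lipid-associated genes numbered 0 without LL-MG 1 or LL-MG 2, 2 without LL-MG 3 or MG 2, 1 without MG 3 and 8 without MG 1. The higher microglia genes numbered 15 without MG 1 and 0 without any other library, by edgeR.

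Averaged over both lineages, Abca1 (0.61 ± 0.08), Apoe (0.52 ± 0.08), Plin2 (0.55 ± 0.09), Lrp1 (0.48 ± 0.07), Angptl4 (0.56 ± 0.07), Acadl (0.48 ± 0.07) and Ppard (0.40 ± 0.06) rose, each with an adjusted p of at most 0.000141 in edgeR. Cd63 (0.57 ± 0.06), Ctsd (0.60 ± 0.07), Gpnmb (0.60 ± 0.10), Trem2 (0.63 ± 0.14) and Lpl (0.99 ± 0.24) rose as well, as did the matrix genes Timp2 (0.80 ± 0.07), Plau (0.64 ± 0.09) and Thbs1 (0.60 ± 0.09). Abcg1 (0.27 ± 0.08), Fabp5 (0.32 ± 0.09), Nr1h3 (0.17 ± 0.06) and Cd36 (0.23 ± 0.09) passed narrowly (adjusted p = 0.0134 to 0.0441 in edgeR). Spp1 (0.02 ± 0.12) and Pparg (-0.08 ± 0.07) did not pass, and the sign of Spp1 turned without LL-MDM 1 (-0.01), LL-MG 3 (-0.06) or MDM 3 (-0.01). The region inside Gramd1b (chromosome 9, 40321003 to 40321926; 1.51 ± 0.10) rose, and a region 6112 bp from Stk17b (chromosome 1, 53791349 to 53792198; -2.40 ± 0.21) fell.

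The lipid-associated list had 11 of 20 members higher and 0 lower (12 and 0 adjusted over the list alone). Limma's camera called the list, with adjusted p = 0.000863 and adjusted p = 0.0488 with an estimated correlation. Microglia genes had 9 of 18 higher (limma's camera, adjusted p = 0.00324; adjusted p = 0.398 with an estimated correlation), matrix genes 8 of 15 (limma's camera, adjusted p = 0.00372; adjusted p = 0.318 with an estimated correlation) and lysosome genes 9 of 20 with 1 lower (limma's camera, adjusted p = 0.0202; adjusted p = 0.318 with an estimated correlation), in each case with the same counts adjusted over the list alone. Antigen presentation had 5 of 15 lower and 0 higher (5 and 0 adjusted over the list alone), a fall seen in LL-MDM but not LL-MG. Limma's camera gave adjusted p = 0.00315 (0.318 with an estimated correlation). PPAR genes had 7 of 15 higher and 1 lower (7 and 1 adjusted over the list alone), at adjusted p = 0.0268 in limma's camera and adjusted p = 0.318 with an estimated correlation, and cholesterol efflux genes 6 of 14 higher and 1 lower (7 and 1 adjusted over the list alone). In limma's camera the set had adjusted p = 0.0346, and adjusted p = 0.318 with an estimated correlation. Lipid uptake genes had 8 of 17 higher and 1 lower (8 and 2 adjusted over the list alone). Its camera call in limma had adjusted p = 0.0495, and adjusted p = 0.318 with an estimated correlation. Interferon genes had 5 of 15 higher and 0 lower (6 and 1 adjusted over the list alone). The camera test of limma gave adjusted p = 0.0495, and adjusted p = 0.318 with an estimated correlation.

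In limma's camera the cholesterol efflux list lost its call without LL-MDM 2 (adjusted p = 0.0739), LL-MG 2 (0.0541) or MDM 2 (0.0571), the lipid uptake list without LL-MDM 2 (0.0586), LL-MG 1 (0.0557), LL-MG 2 (0.0541) or MDM 2 (0.0629) and the lysosome list without MG 2 and MG 3 (0.0759). The interferon list lost it without LL-MDM 2, LL-MG 1, LL-MG 2, MDM 2, MDM 3, MG 1, MG 2 or MG 3 (0.0518 to 0.0970), without MG 2 and MG 3 (0.272) and with thinned libraries (0.194), and the lipid uptake list with thinned libraries (0.276). The monocyte-derived identity list gained a call without LL-MDM 1 (0.0499), LL-MDM 2 (0.0459), MDM 3 (0.0428), MG 1 (0.0135) or MG 2 (0.0397), T and NK cells without MG 2 (0.0444) and dendritic cells without MG 2 and MG 3 (0.0296). The higher matrix genes numbered 5 without MDM 2. In edgeR, Abcg1 lost its call without LL-MDM 2 (0.0688), LL-MG 1 (0.0762), LL-MG 2 (0.0555), MDM 3 (0.0562) or MG 3 (0.0614), and Fabp5 without LL-MG 2 (0.0512). Cd36 lost it without any library but LL-MG 2, MG 1 or MG 3 (0.0595 to 0.131), and Nr1h3 without LL-MDM 1, LL-MDM 2, LL-MG 2, LL-MG 3, MDM 1, MDM 2 or MG 2 (0.0510 to 0.105). These 4 genes also lost their calls with thinned libraries and without MG 2 and MG 3.

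In all, 21978 regions passed for the average, 11579 higher and 10399 lower (14462 without LL-MDM 2), and 4975 genes, 2691 higher and 2284 lower. Across 77737 regions, which are not independent replicates, the lipid-load differences of the lineages correlated with r = 0.243 (Spearman's rho 0.284), and 60.0% had the same sign. Across genes r was 0.280 (rho 0.330). Regions higher in both lineages numbered 1604 and regions lower in both 1168, where independent lists would share 506 and 878, and 482 were called in opposite directions. Without MG 2 and MG 3 the correlation over regions was 0.0921.

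Whether lipid load acted alike in the lineages was tested as an interaction, where a positive value means a higher difference in microglia. The MHC class II genes H2-Eb1 (2.29 ± 0.17), H2-Aa (2.21 ± 0.18) and Cd74 (1.34 ± 0.13) had positive values. Their levels fell in LL-MDM and lay at 24.9 ± 4.83 and 27.6 ± 1.80 CPM in MG and LL-MG for H2-Aa. Ccr7 (2.29 ± 0.25), Flt3 (1.13 ± 0.15), Itga4 (0.73 ± 0.17), Clec7a (1.04 ± 0.22) and Nr1h3 (0.50 ± 0.12) were positive too. Sall1 (-2.84 ± 0.44), Tmem119 (-0.85 ± 0.17) and Gpnmb (-0.74 ± 0.20) were negative, with larger differences in MDM. Each passed with an adjusted p of at most 0.0241 in edgeR. Against MDM mixed with LL-MG reads the rise of Sall1 in LL-MDM was not seen (-0.38, adjusted p = 0.161 in edgeR). The Sall1 interaction therefore cannot be told from microglia reads in the LL-MDM libraries. A region inside Ccdc149 (chromosome 5, 52385900 to 52386538; 3.26 ± 0.37) fell in LL-MDM (31.8 ± 2.17 to 10.3 ± 1.53 CPM) and was at 2.76 ± 0.571 and 8.41 ± 3.32 CPM in MG and LL-MG. A region inside Mms19 (chromosome 19, 41973938 to 41974399; -4.15 ± 0.42) went from 0.426 ± 0.0940 to 9.62 ± 3.14 CPM in MDM.

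Antigen presentation had 9 of 15 members positive and 0 negative (9 and 0 adjusted over the list alone). With limma's camera adjusted p = 3.57e-11 was found, and adjusted p = 0.220 with an estimated correlation. Dendritic-cell markers had 5 of 8 positive and 0 negative (5 and 0 adjusted over the list alone), at adjusted p = 0.000651 in limma's camera and adjusted p = 0.153 with an estimated correlation, and interferon genes 1 of 15 positive and 0 negative (2 and 0 adjusted over the list alone). Limma's camera called the list, with adjusted p = 0.00309 and adjusted p = 0.426 with an estimated correlation. The dendritic-cell count was 3 without LL-MDM 1, LL-MDM 2, LL-MDM 3, LL-MG 1, LL-MG 2, MDM 1 or MG 3 and 2 without LL-MG 3, and the interferon count 2 without LL-MDM 3, 6 without MG 1 and 2 without MG 2. Without MG 2 and MG 3 the interferon list lost its camera call (adjusted p = 0.0944) and the microglia list gained one (0.000626). In edgeR, Gpnmb lost its call without LL-MDM 1 (adjusted p = 0.0510), LL-MDM 3 (0.0519) or LL-MG 3 (0.0772), Itga4 without LL-MG 1 (0.0606) or LL-MG 2 (0.0542) and Nr1h3 without LL-MG 2 (0.0569) or without MG 2 and MG 3 (0.0776). With thinned libraries Clec7a (0.0542), Gpnmb (0.201) and Nr1h3 (0.112) lost theirs.

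Over all regions 8467 passed the interaction test, 3544 positive and 4923 negative, and over all genes 1356, 924 positive and 432 negative. The region count was 3831 without LL-MDM 2, 5118 without LL-MDM 3, 5228, 5300 and 4786 without LL-MG 1, 2 or 3, 5468 and 5436 without MDM 1 or 2, 17816 without MG 1 and 4844 without MG 2 and MG 3. The gene count was 822 and 717 without LL-MDM 2 or 3, 782, 713 and 812 without LL-MG 1, 2 or 3, 796 and 879 without MDM 1 or 2, 3462 without MG 1 and 819 without MG 3.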

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

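The tests of the 3 patterns weighed here and the counts over other splits of the libraries were chosen after the results were seen, while the interaction tests were fixed before the data were examined. The results given first stood out because the lipid-load difference itself differed between the lineages. All of them rest on the groups that the library names give. The interaction test called 8467 regions and 1356 genes in edgeR. Limma's camera called antigen presentation (adjusted p = 3.57e-11; adjusted p = 0.220 with an estimated correlation), dendritic-cell markers (adjusted p = 0.000651; adjusted p = 0.153 with an estimated correlation) and the interferon response (adjusted p = 0.00309; adjusted p = 0.426 with an estimated correlation). Of the 44 genes named for a lipid-load comparison or for the interaction, 22 passed the interaction test, 14 with positive and 8 with negative values. Part of the 44 were named because they passed this test, so the count says nothing of lipid-load genes in general. Over all genes 1356 of 15552 passed.

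Positive log2 values, where the difference was higher in microglia, were 2.29 for Ccr7, 2.29 for H2-Eb1, 2.21 for H2-Aa, 1.49 for H2-Ab1, 1.38 for Ciita, 1.34 for Cd74, 1.13 for Flt3 and 1.04 for Clec7a. They were 0.95 for Bst2, 0.80 for Plac8, 0.73 for Itga4, 0.50 for Nr1h3, 0.41 for Srebf2 and 0.38 for Zbtb46. Negative values were -0.50 for Cd63, -0.56 for Timp2, -0.60 for Ctsd, -0.63 for Ccl4, -0.74 for Gpnmb, -0.85 for Tmem119, -1.48 for Apoc1 and -2.84 for Sall1. The region inside Ccdc149 had 3.26 and the one inside Mms19 -4.15. In edgeR, calls were lost without single libraries for Gpnmb (LL-MDM 1, adjusted p = 0.0510; LL-MDM 3, 0.0519; LL-MG 3, 0.0772), Itga4 (LL-MG 1, 0.0606; LL-MG 2, 0.0542), Nr1h3 (LL-MG 2, 0.0569) and Ctsd (LL-MDM 2, 0.0883). They were lost for Timp2 without LL-MDM 2, LL-MG 3 or MDM 1 (0.0506 to 0.0815), for Plac8 without LL-MDM 3, LL-MG 1, LL-MG 2 or MDM 1 (0.0587 to 0.0790) and for Srebf2 without LL-MDM 1, LL-MDM 3, LL-MG 2, LL-MG 3, MDM 1 or MG 3 (0.0508 to 0.110). Apoc1 lost its call without LL-MDM 1, LL-MDM 2, LL-MDM 3, LL-MG 1, LL-MG 3 or MDM 1 (0.0505 to 0.112), Ccl4 without any library but MG 1 or MG 2 (0.0585 to 0.126) and Zbtb46 without any but MDM 2, MG 1 or MG 2 (0.0525 to 0.125). With thinned libraries Apoc1, Bst2, Cd63, Clec7a, Ctsd, Gpnmb, Nr1h3, Srebf2, Timp2 and Zbtb46 lost theirs (0.0542 to 0.547), and without MG 2 and MG 3 Ccl4, Nr1h3, Srebf2 and Zbtb46 did (0.0776 to 0.193).

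Accessibility of LL-MDM lay between that of MDM and microglia, on the first principal component and at Sall1. Microglia reads in the LL-MDM libraries are argued against as the whole cause by 339 regions specific to MDM. There the LL-MDM libraries kept 30.2 ± 2.14% (SD, n = 3) and at most 32.6% of the MDM level, where a mixture would keep 85.1%. Against the mixed reference 11 lipid-associated genes were higher, and so were 5 of the 7 microglia list genes that rose, Tmem119 (1.04 ± 0.09) among them. This bears on the rise of these genes. It does not decide a position between the groups, and Tmem119 was not higher in LL-MG than in LL-MDM. Lower depth is argued against by MDM 3, which had 6341183 counts and a microglia share of -0.546%, while LL-MDM 2 had 7390521 counts and 18.1%. At the regions specific to microglia and at Sall1 and Sall3, mixed reads and an opening of these regions in the MDM cannot be told apart, because the share mixed in was set from these regions, and 12.4% of the 370 tested of the 796 regions differed from the mixed reference. An effect of lipid load itself, the difference the design names, may account for the rest and was not tested otherwise.

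MHC class II and dendritic-cell loci were lower in LL-MDM than in MDM. Microglia reads and lower depth are argued against as the whole cause, since the median log2 fold change of the 6 called MHC class II loci was -1.11 (median SE 0.08) against the mixed reference and -1.30 (0.12) with thinned libraries, from -1.27 (0.10). Dendritic cells collected with the MDM, and lower accessibility of these loci within lipid-laden MDM, the difference the design names, cannot be told apart, because the 6 of 8 dendritic-cell markers lower in LL-MDM are part of the pattern itself. Zbtb46, Flt3 and Ccr7 stood at 269, 180 and 78.8 CPM in MDM. None of the markers is on another list (0), but 6 of the 8 also exceeded 20 CPM in MG, Zbtb46 and Flt3 with 256 and 61.7 CPM, and the sort gates that would remove such cells are not given in the sources used here.

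MG 2 and MG 3 stood apart from MG 1 and from the other groups. Markers of the 9 other cell types argue against reads of other cells in general, with 7.14% of 70 higher in both libraries than in the other 10, against 8.32% of all genes, and greater depth is argued against because 90.9% of the 11 basophil and mast cell genes measured after thinning were still higher. Basophils or mast cells in these libraries are a candidate explanation, as 71.4% of the 7 measured genes listed for these cells without having been seen to stand apart were higher in both, though 1 of the 7, Kit, had been seen among the genes of the first principal component, and the whole list, 81.2% of 16 measured of 21, was written after the pattern was seen and holds 6 genes seen to show it. Levels in MG 2 and MG 3 were 221 and 142 CPM for Cd200r3, 197 and 115 for Hdc and 116 and 83.0 for Gata2, with at most 124, 55.0 and 50.2 elsewhere; 1 member is on another list, 7 exceeded 20 CPM in LL-MG, and the sort gates are not given in the sources used here. No biological explanation was tested, since the labels name no difference among the MG libraries.

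Splits of the 6 libraries of 2 groups number 10, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each of the 4 pairs of groups. Real and highest other region counts were 22966 and 0 for LL-MDM against MDM, 9502 and 1377 for LL-MG against MG, 40163 and 0 for MG against MDM, and 16704 and 0 for LL-MG against LL-MDM. For genes the real counts were 3708, 2847, 6375 and 3158 in the same order, and the highest other count was 0 in each. For the average, 1 of 100 splits drawn from 200, the real one, gave 21978 regions (highest other 15463) and 4975 genes (highest other 3049), which excludes a chance assignment of the lipid labels. For the interaction 3 of the 100 gave as many as the real 8467 regions and 1356 genes, the highest other being 15463 and 3049. Exchanging lipid labels removes the lipid-load difference itself, so this says nothing of whether the lineages differ in it. Nor does it exclude a chance assignment of the microglia labels. The splits with more calls kept the MDM labels and exchanged those of 4 microglia libraries. A lipid-load difference in both lineages then counts as an interaction.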

How the results depend on the processing

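The thinned libraries, the fits with 1 MG library, the regions named in all 4 groups and the mixed reference are tests chosen after the results were seen; all other settings were fixed before the data were examined. For the 172 differences at genes and regions given in the text, 508 values were recomputed under the planned settings that keep the groups and every library in them. The 148 at genes were run under RLE factors and the replicate block alone, the 24 at regions under these and 6 other scalings, filters and tools, and 20 of these also with only the groups compared. Of these 505 kept their direction and their side of the threshold, 2 newly passed and 1 was lost. All of these changes came from the replicate block (Tmem119 for LL-MG against LL-MDM at adjusted p = 0.0417 and Trem2 for LL-MG against MG at 0.0252 newly passed, and Zbtb46 for the interaction was lost at 0.0642, edgeR). Leaving out each library gave 1314 values, of which 1213 were unchanged in call and direction, 92 lost and 4 gained a call and 5 changed sign. Over all settings but the titles' groups, 1987 of 2154 values were unchanged in this sense, 148 lost and 9 gained a call and 10 changed sign. Depth limits the smallest changes: the LL-MDM libraries hold 1162969 to 7390521 counts, and thinning every library to 1162969 left fewer calls in each comparison.

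With the groups as the titles give them, edgeR called 0 regions for MG against MDM (183 at an unadjusted p under 0.05), 0 for LL-MG against LL-MDM (857) and 0 for the interaction (429). It called 0 genes in the same 3 tests (61, 106 and 43 at an unadjusted p under 0.05), and no other tool was used to call regions or genes with these groups. LL-MDM against MDM gave 13770 regions and 2001 genes, and LL-MG against MG 1144 genes. Lists called by limma's camera numbered 2 for MG against MDM, 2 for LL-MG against LL-MDM, 7 for LL-MG against MG and 5 for the average, and the correlation of the lipid-load differences was 0.905. Of the 172 values 24 were unchanged in call and direction, 97 lost and 1 gained a call, and 50 changed sign. For LL-MDM against MDM the log2 fold changes that turned were Abca1 -0.11, Arg1 -0.058, Cd36 -0.64, Fabp5 -0.059, Gpnmb -0.61, Spp1 -0.61 and Thbs1 -0.86. For LL-MG against MG they were Abca1 -0.28, Bst2 -0.40, Ccl4 1.17, Cd36 -0.66, Ciita -0.40, Fabp5 -0.21, Gpnmb -1.04, Il1rn -0.54, Lrp1 -0.081, Nr1h3 -0.42, Thbs1 -0.71, Nr1h3 (region) -0.91 and Serinc3 (region) 0.69, and for the average Abca1 -0.19, Cd36 -0.65, Fabp5 -0.14, Gpnmb -0.83, Lrp1 -0.015, Nr1h3 -0.45, Spp1 -0.61 and Thbs1 -0.79. For MG against MDM they were Ccl3 -0.063, Ccl4 -0.077, Ccr2 -0.34, Cd36 0.00098, Col4a1 0.046, Il10 0.036, Sall3 -0.015, Tnf -0.10, Kcnma1 (region) -0.18 and Sall1 (region) -0.28, and for LL-MG against LL-MDM Ccr2 0.28, Cd44 0.035, Col4a1 0.19, Ctsd -0.0023, Fn1 0.034, Itga4 0.19, Olr1 0.18, P2ry12 -0.33, Sall1 -0.33, Slc1a3 -0.21 and Rbfox1 (region) -0.017, and for the interaction Ccl4 0.17. The cause is the other assignment of 8 libraries.

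Thinning to the smallest total left 5269 regions and 1553 genes for LL-MDM against MDM, 2554 and 1167 for LL-MG against MG, 11306 and 3500 for MG against MDM, 6137 and 2373 for the average, and 1405 and 464 for the interaction. For LL-MG against LL-MDM it left 5673 regions. Fabp5 (-0.058) and Pparg (0.0043) turned for LL-MDM against MDM. Fewer counts are the construction of this setting. Without MG 2 and MG 3, edgeR called 42 regions and 16 genes for LL-MG against MG, 11718 regions and 2659 genes for the average and 4844 regions for the interaction, the correlation was 0.0921, and Ccr2 for MG against MDM was -1.28. These fits leave MG 1 as the only MG library, assumed to vary like the other groups. With MG 2 or MG 3 as the only one, LL-MG against MG gave 26909 and 9325 regions and 6400 and 2805 genes, and the cause was not tested. With a log2 fold change of at least 1 the region counts were 13841 for LL-MDM against MDM, 5003 for LL-MG against MG, 25480 for MG against MDM and 8071 for the average. With only the regions named in all 4 groups they were 9163, 5827 and 15137 for the same 3 comparisons, 4641 for LL-MG against LL-MDM, 10504 for the average and 3995 for the interaction, with fewer regions tested. The share called higher was then 69.8% for LL-MDM against MDM (from 52.2%), 64.5% for MG against MDM (from 51.8%), 43.1% for LL-MG against MG (from 34.5%), 57.5% for LL-MG against LL-MDM (from 48.0%), 62.1% for the average (from 52.7%) and 36.6% for the interaction (from 41.9%). Over TMM, RLE, total counts, loess offsets, DESeq2 and limma-voom this share ran from 46.9% to 54.5% for MG against MDM, 48.0% to 53.2% for LL-MG against LL-MDM, 49.1% to 57.7% for LL-MDM against MDM, 52.7% to 60.0% for the average and 41.7% to 49.5% for the interaction. The region count for LL-MG against MG was 6294 with DESeq2, 6158 with limma-voom and 1851 when only its groups were fitted, and the cause was not tested. Against the mixed reference, Sall1 (-0.38) and Abcg1 (-0.0045) turned for LL-MDM against MDM. Cd36 (adjusted p = 0.0307) and Fabp5 (0.0119) newly passed in edgeR. The lipid uptake and cholesterol efflux lists gained calls in limma's camera (adjusted p = 0.0288 each). These gains may also come from the fit on MDM and LL-MDM alone.

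With an estimated correlation, limma's camera called 0 lists in 5 of the 6 comparisons. At an unadjusted p under 0.05 there were 4 for LL-MDM against MDM, 3 for LL-MG against MG, 2 for MG against MDM, 4 for LL-MG against LL-MDM and 2 for the interaction. For the average it called 1, the lipid-associated list.

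Leaving out 1 library gave 11846 (LL-MDM 2) to 21831 (LL-MDM 1) regions and 2146 (LL-MDM 2) to 3268 (MDM 3) genes for LL-MDM against MDM, and 3029 (MG 2) to 22310 (MG 1) regions and 999 (LL-MG 1) to 5915 (MG 1) genes for LL-MG against MG. For LL-MG against LL-MDM it gave 10384 (LL-MDM 2) to 14917 (LL-MDM 1) regions, for the average 14462 (LL-MDM 2) to 31622 (MG 1), and for the interaction 3831 (LL-MDM 2) to 17816 (MG 1) regions and 713 (LL-MG 2) to 3462 (MG 1) genes. Called lists numbered 4 (LL-MDM 2 or MDM 2) to 8 (LL-MDM 1) for LL-MDM against MDM and 2 (MG 1) to 5 (LL-MG 3) for LL-MG against MG. Values whose sign changed ran from -0.28 (MG 2) to 0.54 (MG 1) for Ccr2 in MG against MDM, from -0.17 (MG 2) to 0.0047 (MG 3) for Pparg in LL-MG against MG, and from -0.058 (LL-MG 3) to 0.070 (LL-MG 2) for Spp1 in the average. The cause was not tested.

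The runs of 4 consecutive library numbers were used as a replicate block although no label says that they share a mouse. Libraries of the same run deviated from their group means with a median correlation of 0.0276 (-0.0618 to 0.101, with 1 of 18 pairs above 0.1), against -0.0130 for other pairs, so the numbers were not read as pairs. As a hint from the data alone, 10 of the 12 libraries had their highest mean correlation with libraries of their own run. With the replicate block edgeR called 22041 regions for LL-MDM against MDM, 8702 for LL-MG against MG, 39298 for MG against MDM, 15783 for LL-MG against LL-MDM, 21835 for the average and 7595 for the interaction, all within 1.5 times the counts without it, and the correlation was 0.273. Among list calls (limma's camera) the block gave the cholesterol efflux list a call for LL-MDM against MDM (adjusted p = 0.0427), and ended that of the interferon list for MG against MDM (0.0508) and of the lipid uptake list for the average (0.0504), and it changed no other call of a list. RLE factors ended the call of the interferon list for the average (0.0518). Not run were gene sums over promoters alone, another promoter window and the motif settings, which need transcription starts or the genome.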

Other observations

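The lists were fixed before the data were examined, and no test was added for this part. Between MG and MDM several lists had members past the edgeR test but no call in limma's camera. Hypoxia and glycolysis genes were more open in MG at 8 of 18 members and less open at 2 (camera, adjusted p = 0.0964). NF-kB targets had 6 higher and 2 lower of 17 (0.238), PPAR and fatty acid oxidation genes 6 higher and 1 lower of 15 (0.238), and cholesterol efflux genes 6 higher and 2 lower of 14 (0.464), with 6 and 4 adjusted over the list alone. Lipid uptake genes ran the other way, with 1 higher and 7 lower of 17 (0.145). Lysosome genes had 5 higher and 3 lower of 20 (0.548), sterol biosynthesis genes 2 higher and 4 lower of 14 (0.464; 2 and 5 adjusted over the list alone), oxidative stress genes 4 higher and 5 lower of 15 (0.971; 5 and 5 adjusted over the list alone) and proliferation genes 0 higher and 2 lower of 12 (0.464). Where no second pair is given the counts adjusted over the list alone were identical.

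Among lipid-laden cells, NF-kB targets had 5 members higher in LL-MG and 1 lower of 17 (camera, adjusted p = 0.396; 6 and 3 adjusted over the list alone) and lipid uptake genes 0 higher and 5 lower of 17 (0.136; 1 and 5 adjusted over the list alone). With lipid load in microglia, lysosome genes had 5 higher and 1 lower of 20 (0.103), lipid uptake genes 3 higher and 0 lower of 17 (0.103; 7 and 2 adjusted over the list alone), NF-kB targets 2 higher and 3 lower of 17 (0.237; 3 and 6 adjusted over the list alone) and the immunosuppression list 4 higher and 2 lower of 14 (0.121; 5 and 2 adjusted over the list alone). Markers of T and NK cells were lower at 3 of 10 in LL-MG (0.179; 4 adjusted over the list alone), those of neutrophils at 2 of 7 (0.222; 3 adjusted over the list alone), and those of astrocytes higher at 3 of 8 (0.103). Averaged over both lineages, T and NK cell markers were lower at 5 of 10 (0.0986) and proliferation genes at 4 of 12 and higher at 1 (0.119).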
